A study of Mus musculus with 6 samples.

How the data were processed

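RNA sequencing of mouse bone marrow-derived macrophages treated for 24 h was analysed in 6 libraries, 2 each for vehicle, LTα1β2 and LCL161 plus LTα1β2. Groups were taken from the sample titles. The deposited table holds expected counts per gene for all 6 libraries, unnormalised and keyed by gene symbol, with 66.6% of the non-zero values whole and the rest fractions of a read. Per the submitters' processing notes, STAR 2.7.3a, DESeq2 1.26.0 and the genome build GRCm38 were used. Which program counted the reads, with which annotation, how reads with several matches were treated and whether strand was used are not given in the sources used here. Counts of paralogs, and of genes whose exons overlap, are therefore uncertain: among 160 named genes with a position, exons of 14 overlap another gene on the same strand and of 31 on the other strand, and 20 have counts that are not whole in any of the libraries.

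Counts were rounded to whole numbers for the tests. Of 55023 listed genes, 53496 (97.2%) matched the gene name table, and 26 entries with date-like names (24 distinct, 0.106% to 0.178% of counts per library) were kept in the tests and are not named. Positions come from the GENCODE M21 annotation of GRCm38, matched by symbol. The filter filterByExpr (a minimum of 10 reads) left 18812 genes, leaving out 36211. Total counts were 14718368 to 19049613 per library. The TMM factors were 0.874 to 1.15, mitochondrial genes took 0.34% to 0.594% and the 10 most abundant genes 12.3% to 14.9% of the counts. At these totals a floor of 3 reads corresponds to 0.139 to 0.23 CPM. CPM were computed on TMM-scaled library sizes.

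The 3 comparisons were fitted in edgeR 4.0.16 under R 4.3.3 with a group-means model over all 6 libraries (estimateDisp, glmQLFit and glmQLFTest, two-sided), TMM factors and Benjamini-Hochberg adjustment over the genes tested, with calls at an adjusted p under 0.05. The biological coefficient of variation was 13.6%, with 3 residual and 4.59 prior degrees of freedom. Differences between replicates exceeded counting error in each group, with a chi-square per degree of freedom of 15.6 for vehicle, 8.14 for LTα1β2 and 11.9 for LCL161 plus LTα1β2. Gene lists were tested with camera in limma 3.58.1 on voom values (preset correlation 0.01, two-sided), adjusted over 29 lists and 3 comparisons (87 tests), and again with an estimated correlation and with fry. All 46 list calls with the preset correlation were lost with an estimated correlation, where the smallest adjusted p was 0.264. That setting rests on the 3 residual degrees of freedom and can rarely reach small p-values. Its lowest unadjusted camera p over the 87 tests was 0.0125. A call lost there therefore does not show that a list stayed unchanged. Whether the preset correlation holds for these lists was not tested. The camera test compares a list with the other genes, and fry tests whether its members move, on balance, 1 way.

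The 29 lists, 22 of pathways and functions and 7 of markers of other cells, hold 586 entries (567 distinct genes, of which 3 are not in the table) and were fixed, with the tests, the alternatives and the rule for named genes, before the data were examined. Some genes are in more than 1 list. The rule names 9 pathway genes whatever their result, the 6 genes with the largest increase and the 6 with the largest decrease per comparison among called genes whose libraries separate by group, with a mean of at least 5 CPM in the higher group and without predicted gene models, up to 3 members per list with the smallest p, and the most abundant marker of each other cell type. Genes outside this rule are named where a count was 5 or fewer and, in the closing section, for their role, and were chosen after their values were seen. Some genes that the rule selects are not reported here. A further 8 lists (complement, prostanoids and leukotrienes, pattern sensors, C-type lectins, iron handling, endotoxin response, and further stromal genes inside and outside the matrix) were written after the leading genes had been seen and are reported only in the closing section, with their own adjustment.

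A fold against a group with no reads is a lower bound against a floor of 3 reads over the libraries of that group together. With 1 to 3 reads in a group, the ratio of counts is given with a 95% interval for counting error only. The overlap of comparisons that share libraries was set beside 20 simulated sets of unchanged groups, with all libraries drawn anew from the vehicle levels, and beside the overlap of independent lists. Alternatives were relative log expression factors, DESeq2 1.42.0, limma voom, no filter beyond 1 read, at least 1 CPM in 2 libraries, edgeR's newer quasi-likelihood method, a robust fit, only the groups compared, the replicate number as a block, a 2-fold minimum, leaving out each library in turn and, chosen after the data were seen, scaling by total counts and, for the overlap, a vehicle library of its own for each treatment.

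The tests were tried on simulated counts with known changes. Over all genes, edgeR recovered 58.8% of 2-fold and 88.4% of 4-fold changes for LTα1β2 against vehicle (18157 genes), 57.9% and 82.8% for LCL161 plus LTα1β2 against LTα1β2 (18120 genes), and 54.5% and 75.8% for LCL161 plus LTα1β2 against vehicle (18140 genes). For genes of at least 5 CPM it recovered 88.9%, 86% and 89.5% of 2-fold changes and 100% of 4-fold changes in each comparison. Over all genes there were 2 false calls among 143, 10 among 147 and 5 among 131. Few genes were changed in these simulated counts, about as many raised as lowered, and each gene's spread was set to the fitted trend. The rates therefore do not cover changes as many as the 23.4% to 39.5% of genes called in the data, or changes mostly in 1 direction. The requirement on the simulated 4-fold recovery had been set over all genes, was missed in the third comparison and was then restated for genes of at least 5 CPM. Of 29 simulated lists, the 1 that was changed was called and 0 of the 28 unchanged. Simulated genes were drawn independently and only the preset correlation was used. This trial therefore could not show false list calls that arise from correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.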

Results

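Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, which are macrophages grown in culture from marrow precursors. The cells were treated for 24 h in 3 groups of 2 libraries each: vehicle, LTα1β2, or LCL161 together with LTα1β2. LTα1β2 is the lymphotoxin heterotrimer that binds the lymphotoxin beta receptor, and LCL161 is a small-molecule antagonist of the inhibitor of apoptosis proteins cIAP1 and cIAP2. No group received LCL161 alone, so the antagonist can be compared only in the presence of LTα1β2. Total counts were 18860062 and 16902717 in the vehicle libraries, 15958418 and 19049613 with LTα1β2, and 14718368 and 14991252 with LCL161 plus LTα1β2. Reads were counted for 33631 to 40245 of the 55023 listed genes per library. The 18812 genes that passed the filter on low counts held at least 99.5% of the counts. The leading principal component carried 62.5% of the variance and placed the LTα1β2 libraries between those of vehicle and those of LCL161 plus LTα1β2. The second component carried 22.6% and set the LTα1β2 libraries (-41.3 and -72.2) apart from vehicle (38.3 and 27.7) and LCL161 plus LTα1β2 (39.6 and 7.98). Across genes, which are not independent replicates, log2 CPM (read counts scaled to a common library size) of the replicates correlated at 0.985 for vehicle, 0.982 for LTα1β2 and 0.982 for LCL161 plus LTα1β2. The labels do not say whether replicates come from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

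Levels are given as mean CPM ± SD (n = 2 libraries per group), and changes as log2 fold changes with an approximate standard error (SE). This SE is the size of the log2 change divided by the square root of its quasi-likelihood F statistic. For genes with few reads in a group it can be smaller than counting error alone, so it overstates how precisely the largest changes are known. A gene is said to have risen, fallen or changed where edgeR's quasi-likelihood test passed the threshold after Benjamini-Hochberg adjustment, and for every such gene given with its levels, both libraries of 1 group lay above both of the other. Members of the gene lists were counted the same way, and each list was tested as a whole with camera. Its setting with an estimated correlation rests on 3 residual degrees of freedom and can rarely reach small p-values. A list call lost there is therefore left undecided. Genes named because a count was 5 or fewer were chosen after their values were seen.

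**Figure D1:**
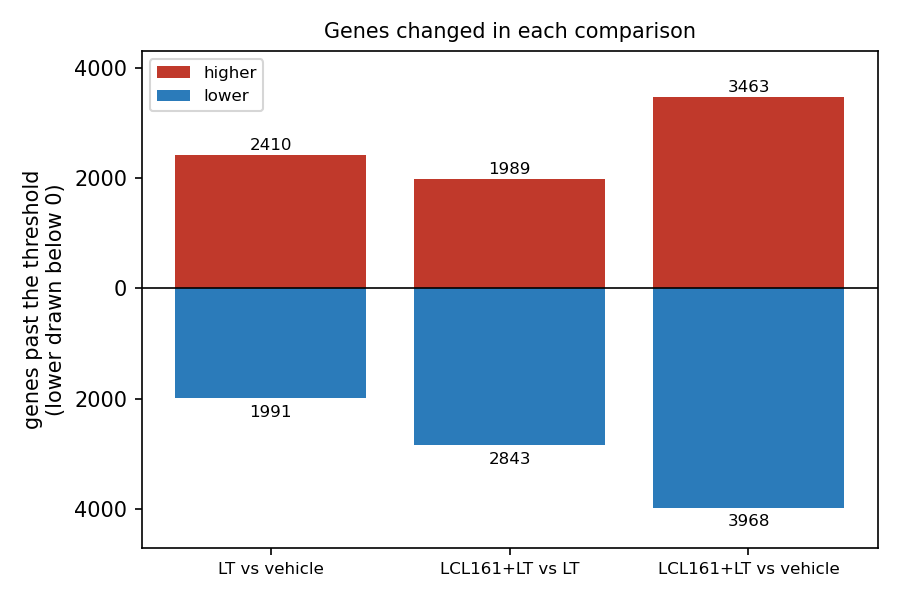
Number of genes higher (above 0) and lower (below 0) in each of the 3 comparisons, by edgeR with all 6 libraries. The bars stand for 2410 higher and 1991 lower genes for LTα1β2 against vehicle, 1989 and 2843 for LCL161 plus LTα1β2 against LTα1β2, and 3463 and 3968 for LCL161 plus LTα1β2 against vehicle. Scaling by total counts shifts the split towards lower genes, to 33%, 28% and 24.6% higher from left to right.

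The first comparison, LTα1β2 against vehicle, asks what the ligand alone changes in these macrophage cultures. Stromal genes were abundant in them (Col1a1 had 59201 and 31441 reads in vehicle), and stromal markers fell in both steps. A change given below can therefore reflect the mix of cells as well as expression in macrophages. All 22 interferon-gamma-type genes and all 21 genes of MHC class I presentation rose, although both list calls were lost with an estimated correlation (adjusted p = 0.264 for each). Gbp4, a guanylate-binding protein induced by interferon gamma, went from 0.76 ± 0.234 to 733 ± 46.5 CPM, and Ciita, the master regulator of MHC class II genes, from 1.57 ± 0.0663 to 156 ± 3.11 CPM. The T cell-attracting chemokine Cxcl9 rose from 0.772 ± 0.0214 to 716 ± 149 CPM, and the checkpoint ligand Cd274 (PD-L1) from 36.9 ± 7.56 to 641 ± 63.4 CPM. Of 30 proliferation genes 16 fell and 2 rose, of 23 cholesterol synthesis genes 10 fell and 1 rose, and of 13 stromal markers 12 fell. These list calls were also lost with an estimated correlation (adjusted p = 0.411, 0.264 and 0.411). In all, 4401 of 18812 genes changed, 2410 of them higher and 1991 lower, and 2106 of these changed by at least 2-fold (1308 higher, 798 lower). The count was 1930 without vehicle replicate 1, 2807 without vehicle replicate 2, 2457 without LTα1β2 replicate 1 and 2499 without LTα1β2 replicate 2. The numbers of higher and lower genes were 1126 and 804, 1550 and 1257, 1722 and 735 (70.1% higher), and 1348 and 1151, in that order. Scaling by total counts, an alternative chosen after the data were seen, called 5565 genes with 33% of them higher, against 54.8% with TMM factors, and moved the median of all genes from -0.039 to -0.23.

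Among the largest increases, Ubd, a ubiquitin-like modifier, had no reads in either vehicle library and was at least 192-fold higher with LTα1β2 (14.4 ± 0.183 CPM), against a floor of 3 reads over both vehicle libraries together. Iigp1 (log2 change 9.67, SE 0.29), Gbp10 (8.69, SE 0.19), Gbp4 (9.88, SE 0.19) and Cxcl9 (9.84, SE 0.23) followed, with edgeR adjusted p from 2e-07 to 1.13e-06. The Toll-like receptor gene Tlr12 had 3 vehicle reads against 1785 with LTα1β2, a ratio of 694 with a 95% counting interval of 237 to 3370, which covers counting error only. The log2 change of Iigp1 was 10.32 without vehicle replicate 1, and that of Tlr12 9.91 without vehicle replicate 2 against 9.30 with all libraries. Exons of Gbp4 overlap those of Gbp8 and Gbp9 on the same strand, and those of Gbp10 overlap Gm43302, so how reads were divided among these genes is uncertain. Among the largest decreases, F13a1, coagulation factor XIII subunit A, fell from 151 ± 62 to 8.5 ± 0.978 CPM (log2 change -4.15, SE 0.30, edgeR adjusted p = 8.04e-05). Nptx1 (log2 change -3.21, SE 0.25) and Adgre4 (-3.16, SE 0.29) also fell, with edgeR adjusted p of 0.000142 and 0.000277. Ibsp, Col8a2 and C1qtnf3, known from bone and connective tissue, had lower levels that rested on widely spaced vehicle libraries: 19.7 ± 21.6, 7.02 ± 8.01 and 5.88 ± 3.2 CPM in vehicle against 0.432 ± 0.0695, 0.373 ± 0.0768 and 0.555 ± 0.424 CPM with LTα1β2. Their edgeR adjusted p of 0.00978, 0.0261 and 0.00723 became 0.0614 for Ibsp and 0.131 for Col8a2 without LTα1β2 replicate 1, 0.064 and 0.126 without LTα1β2 replicate 2, and 0.212 for Col8a2 and 0.0728 for C1qtnf3 without vehicle replicate 1. Over the 16 alternatives of each, adjusted p ran from 4.95e-70 to 0.195 for Ibsp, from 1.23e-25 to 0.252 for Col8a2 and from 4.8e-17 to 0.0728 for C1qtnf3. With a library left out, the log2 change ran from -6.31 to -3.35 for Ibsp (-5.49 with all libraries), from -5.05 to -1.83 for Col8a2 (-4.21) and from -4.51 to -2.66 for C1qtnf3 (-3.35).

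Birc3, which encodes cIAP2, rose with LTα1β2 from 40.2 ± 0.343 to 75.1 ± 0.375 CPM (log2 change 0.90, SE 0.09, edgeR adjusted p = 0.000438). Birc2, which encodes cIAP1, rose from 24.3 ± 0.309 to 35.3 ± 2.06 CPM (0.54, SE 0.10, adjusted p = 0.00927), Ltbr, the receptor gene, from 75.6 ± 1.74 to 99.4 ± 1.75 CPM (0.39, SE 0.10, adjusted p = 0.0259), and Relb, a noncanonical NF-kB subunit, from 33.2 ± 3.04 to 48.3 ± 2.9 CPM (0.54, SE 0.15, adjusted p = 0.0378). Without vehicle replicates 1 and 2 in turn the edgeR adjusted p was 0.0759 and 0.0694 for Birc2, 0.189 and 0.114 for Ltbr, and 0.246 and 0.0863 for Relb. Without LTα1β2 replicates 1 and 2 it was 0.0813 and 0.116 for Ltbr and 0.07 and 0.196 for Relb, and under total-count scaling 0.0547 for Birc2, 0.136 for Ltbr and 0.0771 for Relb. Over 16 alternatives each, adjusted p ran from 0.000988 to 0.0759 for Birc2, from 0.00819 to 0.189 for Ltbr and from 0.000254 to 0.246 for Relb. The log2 changes of Traf3 (0.37), Nfkb2 (0.23), Traf2 (0.15), Map3k14 (0.064, the kinase NIK) and Xiap (-0.042) did not pass, with edgeR adjusted p from 0.0869 to 0.868. Traf3 passed with no filter beyond 1 read (0.0327) and with only the 2 groups compared (0.0477). Of 21 genes of the receptor, cIAP and NF-kB machinery, 8 rose and only Otud7b fell (12 and 1 adjusted over the list alone). The median log2 change was 0.39 (camera adjusted p = 5.12e-05; adjusted p = 0.324 with an estimated correlation). Tnfrsf14 (log2 change 2.55, SE 0.15), Cd40 (2.93, SE 0.19) and Tnfrsf1a (1.11, SE 0.09) had the smallest p in that list. In GRCm38, on the GENCODE M21 annotation, Birc2 lies on chromosome 9 at 7818227 to 7837064, Birc3 on chromosome 9 at 7848699 to 7873186, Ltbr on chromosome 6 at 125306571 to 125313885, and Relb on chromosome 7 at 19606217 to 19629438. Nfkb2 lies on chromosome 19 at 46304320 to 46312385, Traf2 on chromosome 2 at 25517982 to 25546940, Traf3 on chromosome 12 at 111166370 to 111267153, Map3k14 on chromosome 11 at 103219762 to 103267472, and Xiap on chromosome X at 42059679 to 42109656. Exons of Map3k14 overlap 1700028N14Rik on the same strand and those of Nfkb2 overlap Psd on the other strand. The count of Map3k14 is therefore uncertain, and that of Nfkb2 where strand was not used. Counts of Nfkb2 were also not whole in any library.

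**Figure D2:**
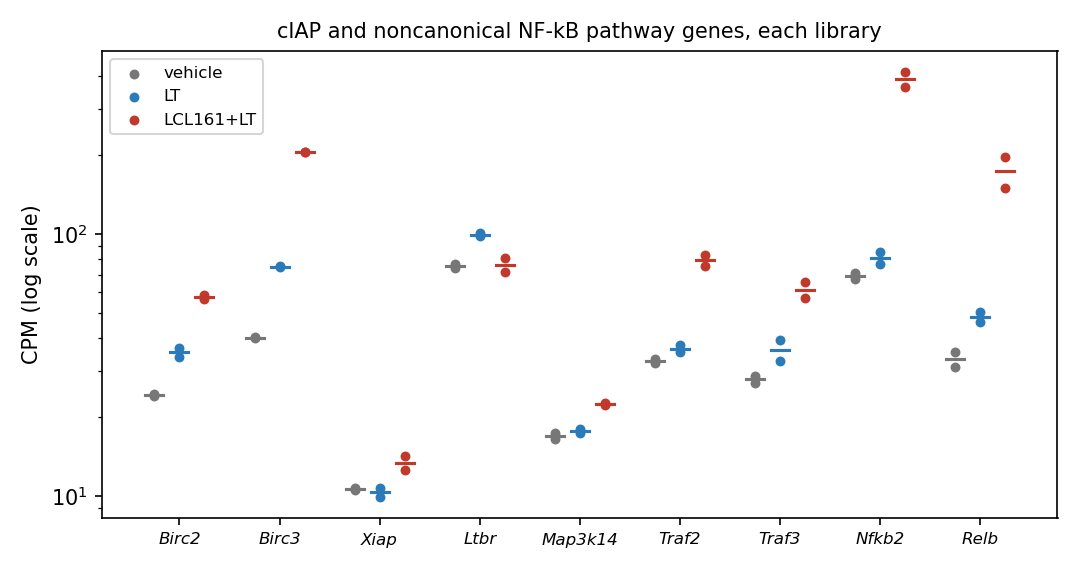
CPM (log scale) of 9 genes of the cIAP and noncanonical NF-kB pathway in each of the 6 libraries; points are libraries and horizontal lines are group means. By group mean, Nfkb2 lies at 69 CPM in vehicle, 81 CPM with LTα1β2 and 388 CPM with LCL161 plus LTα1β2, and Birc3 at 40.2, 75.1 and 205 CPM, while the group means of Xiap stay between 10.3 and 13.4 CPM.

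Interferon-response genes rose with LTα1β2 in nearly every member tested. All 22 interferon-gamma-type genes rose (22 adjusted over the list alone), with a median log2 change of 5.98 (camera adjusted p = 5.23e-29; adjusted p = 0.264 with an estimated correlation). The GTPases Gbp6 (log2 change 8.41, SE 0.16), Gbp4 and Igtp (5.75, SE 0.13) led by p, and all 3 had counts that were not whole in all 6 libraries. Of 35 interferon-stimulated genes, 33 rose (34 adjusted over the list alone) and none fell, with a median of 2.50 (camera adjusted p = 2.53e-22; adjusted p = 0.379 with an estimated correlation). Stat2, a transcription factor of interferon signalling, rose from 37.3 ± 3.96 to 182 ± 12.7 CPM, and Parp14 from 34.5 ± 6.8 to 246 ± 18.9 CPM. Exons of Parp14 overlap a predicted gene on the same strand. Ifi27l2a (log2 change 1.13) and Isg20 (-0.05) did not pass. All 21 genes of MHC class I presentation rose (21 adjusted over the list alone), with a median of 2.73 (camera adjusted p = 2.12e-26; adjusted p = 0.264 with an estimated correlation). Examples are the peptide transporter Tap1 (log2 change 4.49, SE 0.14), the immunoproteasome subunit Psmb8 (3.05, SE 0.12) and H2-T23 (3.83, SE 0.12), whose counts were not whole in any library. Of 13 class II genes, 11 rose (12 adjusted over the list alone) and none fell, with a median of 4.18 (camera adjusted p = 2.23e-13; adjusted p = 0.324 with an estimated correlation). Ciita rose 6.63 (SE 0.13) on the log2 scale, H2-DMa 4.62 (SE 0.18) and H2-Aa 4.49 (SE 0.22), while H2-Ob (1.46) and Lgmn (0.08) did not pass. Of 19 costimulatory and checkpoint genes, 8 rose and Cd80 fell (8 and 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00732; adjusted p = 0.346 with an estimated correlation). Cd274 (log2 change 4.12, SE 0.17), Slamf7 (2.28, SE 0.12) and Cd86 (2.23, SE 0.13) led that list. Counts of Cd274 were not whole in any library, nor were those of Sod2.

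The list called classical NF-kB feedback genes mixes feedback inhibitors, such as Nfkbia and Tnfaip3, with other NF-kB targets, such as Icam1, Sod2 and Ptgs2. Of its 24 genes, 9 rose and Ptgs2 and Ier3 fell with LTα1β2 (11 and 2 adjusted over the list alone). Across the 24 genes the median was 0.33 (camera adjusted p = 0.00134; adjusted p = 0.552 with an estimated correlation). Icam1, an adhesion molecule, rose from 70.7 ± 7.34 to 319 ± 12.1 CPM and Sod2 from 155 ± 8.45 to 444 ± 33 CPM, and Ptgs2, the inducible cyclooxygenase, fell from 122 ± 7.19 to 51.4 ± 6.46 CPM. Without LTα1β2 replicate 2 the adjusted p of that list was 0.0547, by fry 0.0515, and over its 12 alternatives it ran from 3.07e-06 to 0.552. Of 7 genes known as noncanonical NF-kB targets, Tnfsf13b and Vcam1 rose and Cxcl12 and Tnfsf11 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.897). Cxcl12 is also in the list of stromal markers. Of 20 cytokine genes, 6 rose and Csf1 and Osm fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0954), led by Il27 (log2 change 3.84, SE 0.17), Tnf (1.92, SE 0.13) and Tnfsf10 (4.68, SE 0.36). The change of Tnfsf10 was 6.09 without vehicle replicate 1 and 4.04 without vehicle replicate 2, and the cytokine list passed without LTα1β2 replicate 1 (adjusted p = 0.0376). Of 21 chemokine genes, 9 rose and 5 fell, Ccl9, Cxcl2, Ccl6, Ccl3 and Cxcl1 (9 and 6 adjusted over the list alone; camera adjusted p = 0.451), and their median of 0.15 was -0.039 under total-count scaling. Ccl5 rose from 3.03 ± 0.154 to 175 ± 48.5 CPM, and Ccl8 had 2 vehicle reads against 461 with LTα1β2, a ratio of 269 (95% counting interval 74 to 2230).

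Of 32 phagocytic receptor genes, 11 rose and 4 fell with LTα1β2 (12 and 5 adjusted over the list alone; camera adjusted p = 0.0313; adjusted p = 0.426 with an estimated correlation), with a median of 0.12 that was -0.071 under total-count scaling. The adjusted p of that list was 0.0827 under total-count scaling and 0.0668 without vehicle replicate 1, and ran from 2.3e-05 to 0.426 over its 12 alternatives. The Fc receptors Fcgr4 (log2 change 4.01, SE 0.10) and Fcgr1 (2.57, SE 0.10) rose, and the efferocytosis ligand Gas6 fell with Mrc1, Colec12 and Cd14 (Gas6 -2.08, SE 0.11). Of 29 lysosomal genes, 13 rose and Atp6v0d2, Ctsl and Ctsk fell (15 and 5 adjusted over the list alone). Lysosomal genes had a median of 0.35 (camera adjusted p = 0.000975; adjusted p = 0.572 with an estimated correlation; fry 0.083), and the adjusted p ran from 1.4e-09 to 0.572 over 12 alternatives. The cathepsin gene Ctsh rose from 388 ± 72.4 to 1202 ± 80.9 CPM. Of 23 macrophage lineage genes, 13 rose and Cx3cr1, Trem1 and Maf fell (14 and 5 adjusted over the list alone). For this lineage list the median was 0.70 (camera adjusted p = 0.000772; adjusted p = 0.467 with an estimated correlation), including Ly6c2 (2.88, SE 0.16) and C1qa (1.13, SE 0.10). Of 17 genes of alternative activation, 4 rose (Il4ra, Arg1, Ccl22 and Pdcd1lg2) and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.192), led by Fcrls (-2.34, SE 0.10), Tfrc (-1.76, SE 0.10) and Mrc1 (-2.02, SE 0.14). Of 13 osteoclast and fusion genes, Ocstamp, Tnfrsf11a and Fos rose and Atp6v0d2, Ctsk, Acp5, Itgb3 and Mmp9 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.664). Of 27 cell death genes, 10 rose and Pmaip1 and Bcl2 fell (10 and 2 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.000226; adjusted p = 0.324 with an estimated correlation). Those that rose included the pyroptosis genes Casp1 (2.09, SE 0.10) and Gsdmd (1.69, SE 0.11) and the necroptosis gene Mlkl (1.76, SE 0.15).

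Of 30 proliferation genes, 16 fell and Pcna and E2f1 rose with LTα1β2 (20 and 2 adjusted over the list alone). Proliferation genes had a median of -0.71 (camera adjusted p = 9.78e-08; adjusted p = 0.411 with an estimated correlation). Ccnb1 fell from 112 ± 14 to 51.4 ± 3.34 CPM, Cdc20 from 77 ± 9.99 to 37.8 ± 3.39 CPM and Ube2c from 56.3 ± 7.18 to 26.4 ± 3.21 CPM. Counts of Ccnb1, and those of the stromal marker Acta2, were not whole in any library. In the same libraries, 12 of 13 stromal markers fell (12 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 1.04e-07; adjusted p = 0.411 with an estimated correlation), and the other, Dcn, had a log2 change of 0.14. The most abundant stromal marker, the smooth muscle actin gene Acta2, fell from 2516 ± 407 to 1000 ± 185 CPM. Of 23 cholesterol synthesis genes, 10 fell and Ebp rose (12 and 1 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 0.000166; adjusted p = 0.264 with an estimated correlation), and those that fell included Cyp51 (-0.75, SE 0.09), Sqle (-0.65, SE 0.09) and Hsd17b7 (-0.79, SE 0.11). Of 13 LXR targets, Abcg1 rose and Scd1, Abca9, Scd2 and Fasn fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.7). Of 26 genes of glycolysis and hypoxia, 7 rose and Adm and Ndrg1 fell (11 and 3 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.012; adjusted p = 0.552 with an estimated correlation). Its adjusted p was 0.105 without LTα1β2 replicate 2 and 0.0994 under total-count scaling, and ran from 3.14e-06 to 0.552 over 12 alternatives. Of 20 genes of the unfolded protein response, Sdf2l1, Edem1 and Atf3 rose and Asns and Herpud1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.683).

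Of 18 NRF2 and oxidative stress genes, 5 rose with LTα1β2 (Prdx1, Gsr, Slc48a1, G6pdx and Gclm) and Cat, Nqo1 and Mt1 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.7). Calls of Edem1 and Gsr were lost without vehicle replicate 1 (edgeR adjusted p = 0.0511 and 0.0622), of Asns without LTα1β2 replicate 1 (0.0622), and of Cat without LTα1β2 replicates 1 and 2 (0.052 and 0.0518). Over their 16 alternatives, adjusted p ran from 1.69e-12 to 0.0511 for Edem1, 5.26e-21 to 0.0622 for Gsr, 3.32e-07 to 0.0622 for Asns and 1.13e-09 to 0.052 for Cat. Of the markers of other cells, none of 8 for T and NK cells changed (0 adjusted over the list alone; camera adjusted p = 0.947), and Il7r, the most abundant, was at 44.7 ± 4.85 CPM in vehicle and 48.5 ± 16.7 CPM with LTα1β2. Of 6 B and plasma cell markers, Ebf1 fell (1 adjusted over the list alone; camera adjusted p = 0.804). Of 14 neutrophil markers, 5 rose (S100a8, Csf3r, S100a9, Ly6g and Cxcr2) and Retnlg fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.277, and 0.0102 without vehicle replicate 2). Of 13 dendritic cell markers, Bst2, Clec9a, Itgax and Batf3 rose and Fscn1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.154). Of 7 mast cell, basophil and eosinophil markers, Mcpt8 fell (1 adjusted over the list alone; camera adjusted p = 0.793), and Prg2 was at 1.43 ± 0.338 and 3.26 ± 0.457 CPM without passing, although it passed in 4 of 16 alternatives. Of 8 erythroid and megakaryocyte markers, Pf4, Ppbp and Gp1bb fell (3 adjusted over the list alone; camera adjusted p = 0.0954, and 0.0131 without vehicle replicate 1). Median, mean and test differed in sign for 5 lists in this comparison, none of them called: noncanonical NF-kB targets (median 0.41, mean -0.11), osteoclast genes (-0.36, 0.010), unfolded protein response (0.056, -0.011), B cell markers (0.41, 0.16, test lower) and mast cell markers (0.084, -0.12).

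The second comparison, LCL161 plus LTα1β2 against LTα1β2, asks what the cIAP antagonist adds. Of 24 classical NF-kB feedback genes 18 rose, and of 21 genes of the receptor, cIAP and NF-kB machinery 11 rose and 2 fell (adjusted p = 0.324 for each list with an estimated correlation). Nfkb2 went from 81 ± 6.1 to 388 ± 36 CPM, the adaptor Traf1 from 9.2 ± 3.17 to 235 ± 19.6 CPM, and the costimulatory receptor Cd40 from 36.9 ± 6.46 to 617 ± 55.5 CPM. Of 20 cytokine genes 9 rose and 3 fell (adjusted p = 0.411 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 7.26 ± 2.14 to 487 ± 43.7 CPM and Tnf from 89.3 ± 9.55 to 424 ± 33.9 CPM. Of 30 proliferation genes 28 fell, of 13 stromal markers 12 and of 14 neutrophil markers 8. With an estimated correlation these list calls were lost (adjusted p = 0.324, 0.411 and 0.436), and the neutrophil markers did not pass by fry (0.0535). In all, 4832 genes changed, 1989 higher and 2843 lower, and 2585 of these changed by at least 2-fold (1055 higher, 1530 lower). The count was 2332 without LTα1β2 replicate 2 (736 higher, 1596 lower). The number of higher genes was 1229 without LCL161 plus LTα1β2 replicate 1 and 1288 without replicate 2 (28% of 4604). Under total-count scaling 5448 genes changed with 28% of them higher, against 41.2% with TMM factors, and the median of all genes moved from 0.0045 to -0.12.

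The largest increases were in the chemokine gene Ccl22 (log2 change 6.18, SE 0.23), Nos2 (6.06, SE 0.22), the nonclassical class I gene H2-M2 (5.91, SE 0.14), Clec4e, which encodes the receptor Mincle (5.81, SE 0.16), Susd2 (5.51, SE 0.16) and the neutrophil-attracting chemokine gene Cxcl3 (5.38, SE 0.70). Their edgeR adjusted p ran from 2.84e-06 to 0.00144, and Clec4e reached 3747 ± 6.62 CPM from 66.6 ± 4.69 CPM. Cxcl3 was at 0.638 and 0 CPM in the LTα1β2 libraries, and its log2 change was 4.25 without LTα1β2 replicate 2. Without LTα1β2 replicate 1 no read is left in that group, so no change is given. The largest decreases were in the organic anion transporter gene Slco2b1 (-4.76, SE 0.32), Ccn5 (-4.46, SE 0.48), the constitutive cyclooxygenase gene Ptgs1 (-4.05, SE 0.22), Foxc1 (-3.91, SE 0.48), Sectm1a (-3.83, SE 0.33) and the integrin gene Itgb5 (-3.66, SE 0.48), with edgeR adjusted p from 4.25e-05 to 0.00154. Ptgs1 went from 78.8 ± 5.8 to 4.74 ± 0.525 CPM, and Itgb5 from 449 ± 33 to 35.5 ± 27.5 CPM. Without LCL161 plus LTα1β2 replicates 1 and 2 the log2 change was -3.27 and -5.14 for Foxc1 and -3.05 and -4.87 for Itgb5. Exons of Slco2b1 and Ptgs1 overlap predicted genes on the other strand.

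Birc3 rose further with LCL161, from 75.1 ± 0.375 to 205 ± 0.522 CPM (log2 change 1.45, SE 0.09, edgeR adjusted p = 6.86e-05), and Birc2 from 35.3 ± 2.06 to 57.4 ± 1.21 CPM (0.70, SE 0.10, adjusted p = 0.00253). Traf2 (1.12, SE 0.10), Traf3 (0.76, SE 0.13) and Relb (1.84, SE 0.15) rose with edgeR adjusted p of 0.000344, 0.00549 and 0.000213, and Nfkb2 rose by 2.26 (SE 0.11, adjusted p = 2.8e-05). Map3k14 (0.34, adjusted p = 0.0678, and 0.0405 with a filter of at least 1 CPM in 2 libraries) and Xiap (0.38, adjusted p = 0.0894) did not pass. Ltbr fell from 99.4 ± 1.75 to 76.1 ± 6.46 CPM (-0.39, SE 0.10, edgeR adjusted p = 0.0272). Its adjusted p was 0.0686 without LTα1β2 replicate 1, 0.0974 without LTα1β2 replicate 2 and 0.112 without LCL161 plus LTα1β2 replicate 1, and ran from 0.00233 to 0.112 over 16 alternatives. Of the 21 machinery genes, 11 rose and Tnfrsf1a and Ltbr fell (14 and 2 adjusted over the list alone). The machinery genes had a median of 0.51 (camera adjusted p = 8.64e-06; adjusted p = 0.324 with an estimated correlation). Of 24 classical NF-kB feedback genes, 18 rose (21 adjusted over the list alone) and none fell, with a median of 1.71 (camera adjusted p = 2.6e-18; adjusted p = 0.324 with an estimated correlation). Ptgs2 rose from 51.4 ± 6.46 to 603 ± 8.46 CPM, and the survival genes Bcl2a1a and Bcl2a1d, near-identical copies whose reads cannot be cleanly separated, from 3.68 ± 0.693 to 63 ± 0.727 CPM and from 5.95 ± 1.19 to 69.5 ± 0.158 CPM. Of 7 noncanonical target genes, Vcam1 rose from 80.5 ± 9.5 to 577 ± 25.6 CPM and Cxcl12 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.683). By fry this list passed as higher (adjusted p = 0.0147), although its median was -0.28.

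Of 20 cytokine genes, 9 rose and Vegfa, Csf1 and Tnfsf14 fell with LCL161 (12 and 4 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.00175; adjusted p = 0.411 with an estimated correlation). Il1a (log2 change 4.50, SE 0.22), Tnf (2.25, SE 0.12) and Il12b (4.42, SE 0.31) led that list. Of 21 chemokine genes, 13 rose and Cxcl14, Ccl6 and Cx3cl1 fell (13 and 3 adjusted over the list alone), with a median of 1.77 (camera adjusted p = 1.71e-05; adjusted p = 0.324 with an estimated correlation). Those that rose include Cxcl2 (3.45, SE 0.14) and Ccl3 (2.45, SE 0.14), which had fallen with LTα1β2 alone. Of 19 costimulatory and checkpoint genes, 13 rose and Vsir fell (16 and 1 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 5.67e-09; adjusted p = 0.264 with an estimated correlation). It was led by Cd40, Icam1 (2.26, SE 0.13) and Slamf1 (4.22, SE 0.25). Of 35 interferon-stimulated genes, 21 rose (28 adjusted over the list alone) and none fell, with a median of 1.19 (camera adjusted p = 3.45e-13; adjusted p = 0.415 with an estimated correlation). The increases include the RNA sensor gene Ifih1 (1.76, SE 0.15), Herc6 (1.35, SE 0.14) and Parp14 (1.24, SE 0.15), and exons of Herc6 overlap a predicted gene on the same strand. Of 22 interferon-gamma-type genes, Nos2, Acod1, Batf2 and Gbp5 rose and Gbp8 fell (4 and 1 adjusted over the list alone), with a median of -0.062 and a mean of 0.45 (camera adjusted p = 0.51). Acod1, which makes itaconate, went from 453 ± 40.3 to 3291 ± 29.3 CPM. Of 21 class I genes, 10 rose (15 adjusted over the list alone) and none fell, with a median of 0.38 (camera adjusted p = 5.36e-07; adjusted p = 0.324 with an estimated correlation). Psme2 rose by 1.12 (SE 0.11) on the log2 scale, and H2-Q6 and H2-Q7, paralogs with counts that were not whole in any library, by 2.02 and 2.00 (SE 0.18 each). Of 13 class II genes, Ifi30 and H2-Oa rose and Lgmn and Ciita fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.514).

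Of 30 proliferation genes, 28 fell with LCL161 (30 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 1.64e-17; adjusted p = 0.324 with an estimated correlation), and Ccne2 (-0.72) and E2f1 (-0.42) did not pass over all genes. Cdc20 fell from 37.8 ± 3.39 to 7.84 ± 0.683 CPM, Rrm2 from 126 ± 12.1 to 35.8 ± 4.91 CPM and Ccnb1 from 51.4 ± 3.34 to 15.6 ± 0.734 CPM. Counts of Rrm2 were not whole in any library. In the same libraries 12 of 13 stromal markers fell (12 adjusted over the list alone), with a median of -1.98 (camera adjusted p = 5.54e-08; adjusted p = 0.411 with an estimated correlation), Acta2 to 253 ± 15.9 CPM, while Dcn had a log2 change of 0.30. Of 14 neutrophil markers 8 fell (9 adjusted over the list alone) and none rose, with a median of -1.59 (camera adjusted p = 0.000102; adjusted p = 0.436 with an estimated correlation; fry 0.0535; 7.55e-11 to 0.436 over 12 alternatives). The most abundant of them, S100a8, fell from 290 ± 48.3 to 178 ± 8.29 CPM (edgeR adjusted p = 0.0161, and 0.0596 without LTα1β2 replicate 1; 1.97e-09 to 0.0596 over 16 alternatives). Of 23 macrophage lineage genes, Tlr2 and Adgre1 rose and 12 fell (5 and 12 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0125; adjusted p = 0.572 with an estimated correlation; fry 0.124; 9.45e-09 to 0.572 over 12 alternatives). Among those that fell were Cx3cr1 (-2.06, SE 0.13) and Cd5l (-1.93, SE 0.20). Of 32 phagocytic receptor genes 11 rose and 14 fell (12 and 16 adjusted over the list alone; camera adjusted p = 0.146), led by Fcgr4 (-1.57, SE 0.09), Gas6 (-1.92, SE 0.11) and the mannose receptor Mrc1 (-2.49, SE 0.16).

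Of 29 lysosomal genes, Ctsz, Atp6v1h and Scarb2 rose and Ctsl, Ctsk, Glb1 and Grn fell with LCL161 (3 and 4 adjusted over the list alone; camera adjusted p = 0.51). Of 17 alternative activation genes, Ccl22 and Egr2 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.086). Of 13 osteoclast and fusion genes, 7 rose, including Dcstamp (log2 change 2.89, SE 0.25), Acp5 (1.57, SE 0.14) and Src (2.58, SE 0.24), and Nfatc1, Fos, Itgb3 and Ctsk fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.104). Of 27 cell death genes, 7 rose, led by Fas (1.82, SE 0.13) and Nlrp3 (1.60, SE 0.17), and Ripk3, Bcl2l1 and Pmaip1 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.219). Of 18 NRF2 and oxidative stress genes, 9 rose (10 adjusted over the list alone) and none fell, with a median of 0.44 (camera adjusted p = 9.22e-06; adjusted p = 0.411 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 48.6 ± 2.2 to 850 ± 22 CPM, Sqstm1 from 723 ± 62.2 to 2180 ± 64.1 CPM and Prdx1 from 5976 ± 275 to 18200 ± 453 CPM. Counts of Slc7a11 and Sqstm1, and of Bnip3 in the next list, were not whole in any library. Of 26 genes of glycolysis and hypoxia, 11 rose and Vegfa, Aldoc and Ndrg1 fell (14 and 3 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.000665; adjusted p = 0.438 with an estimated correlation). Increases include Bnip3 (0.92, SE 0.10) and the glucose transporter gene Slc2a1 (0.82, SE 0.10). Of 23 cholesterol synthesis genes, 7 fell and Mvd rose (7 and 1 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.0147; adjusted p = 0.324 with an estimated correlation). Decreases include Dhcr7 (-1.15, SE 0.13). Of 13 LXR targets, Nr1h3 and Abca1 rose and 5 fell, Scd2, Abca9, Fasn, Scd1 and Abcg1 (3 and 5 adjusted over the list alone; camera adjusted p = 0.219). Of 20 genes of the unfolded protein response, Ppp1r15a, Dnajb9 and Ddit3 rose and Sesn2, Asns, Pdia4 and Pdia6 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.999). Calls of Sesn2 and Asns were lost without LTα1β2 replicate 2 (edgeR adjusted p = 0.0874 and 0.0961) and that of Sesn2 without LCL161 plus LTα1β2 replicate 1 (0.0539), and ran from 2.53e-07 to 0.0874 and from 1.93e-07 to 0.0961 over 16 alternatives.

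Of the other cell type markers in this comparison, Cd4 fell among 8 for T and NK cells (1 adjusted over the list alone; camera adjusted p = 0.815), and Ebf1 and Ighm among 6 for B and plasma cells (2 adjusted over the list alone; camera adjusted p = 0.883). Of 13 dendritic cell markers, Itgax, Siglech and Cd209a rose and Fscn1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.072). None of 7 mast cell, basophil and eosinophil markers changed (0 adjusted over the list alone; camera adjusted p = 0.653). Of 8 erythroid and megakaryocyte markers only Pf4 passed over all genes (0 adjusted over the list alone; camera adjusted p = 0.95), and without any 1 of the 6 libraries its edgeR adjusted p lay between 0.0653 and 0.294. The Pf4 call was also lost with the replicate number as a block (edgeR adjusted p = 0.0596), with no filter beyond 1 read (0.282) and under total-count scaling (0.127). Median, mean and test differed in sign for the noncanonical targets (median -0.28, mean 0.19), the interferon-gamma-type genes and the unfolded protein response (-0.042, 0.011). None of these lists was called by camera.

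**Figure D3:**
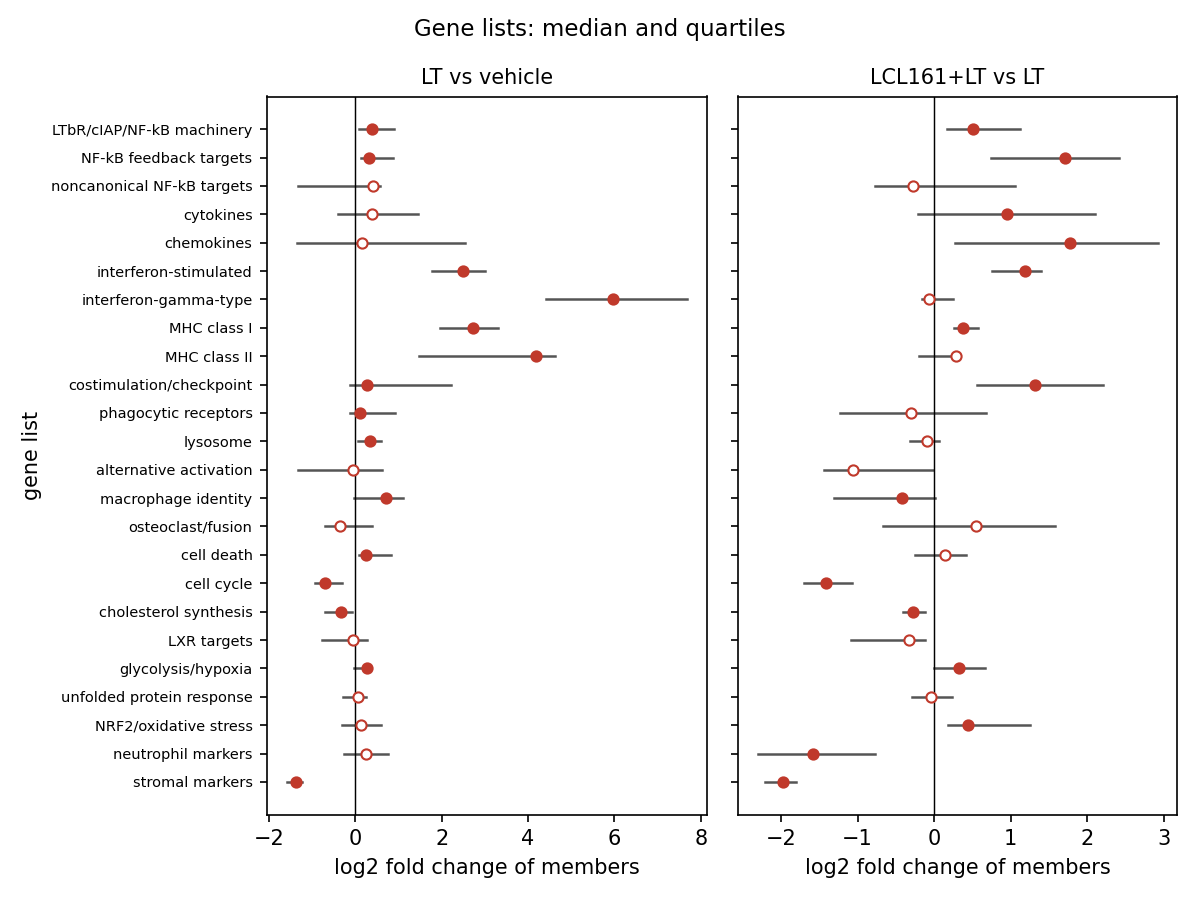
Median (circle) and quartiles (line) of the log2 fold changes of the tested members of 24 gene lists, for LTα1β2 against vehicle (left) and LCL161 plus LTα1β2 against LTα1β2 (right); filled circles passed camera with its preset correlation. The interferon-gamma-type list has medians of 5.98 and -0.062, the NF-kB feedback list 0.33 and 1.71, and the stromal markers -1.37 and -1.98. On the left, the medians of the chemokines, phagocytic receptors, unfolded protein response and NRF2 lists fall below 0 under total-count scaling.

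The third comparison, LCL161 plus LTα1β2 against vehicle, gives the combined treatment. Cxcl9 reached 1413 ± 39.2 CPM from 0.772 ± 0.0214 CPM in vehicle (log2 change 10.82, SE 0.24), Nos2 487 ± 43.7 CPM from 0.44 ± 0.163 CPM (10.06, SE 0.29) and Cst7, the cystatin F gene, 227 ± 9.84 CPM from 0.27 ± 0.0763 CPM (9.66, SE 0.18). Gbp4 rose by 9.76 (SE 0.19), and edgeR adjusted p of these 4 genes ran from 9e-08 to 5.98e-07. Ubd was at least 1660-fold higher than in vehicle, where no read was counted, against the same floor over both vehicle libraries. Apol7c had 2 vehicle reads, both in replicate 1, against 1735 (ratio 1300, 95% counting interval 359 to 10700), and its log2 change was 9.29 without vehicle replicate 2 against 10.15 with both. In all, 7431 genes changed, 3463 higher and 3968 lower, and 4374 of these changed by at least 2-fold (2093 higher, 2281 lower). The count was 4885 without vehicle replicate 1 (1900 higher) and 5284 without vehicle replicate 2 (2060 higher, 39%). Scaling by total counts called 8698 genes with 24.6% of them higher, against 46.6% with TMM factors, moving the median of all genes from 0.047 to -0.26.

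Among the largest decreases against vehicle, F13a1 fell to 3 ± 0.525 CPM (log2 change -5.65, SE 0.34) and Ccn5 from 58.8 ± 27.9 to 1.01 ± 0.193 CPM (-5.86, SE 0.48), with edgeR adjusted p of 1.18e-05 and 5.38e-05. Sp7, the osteoblast transcription factor, had 557 reads in vehicle and 2 with LCL161 plus LTα1β2, a ratio of 186 (95% counting interval 51.2 to 1540). Col8a2 had 299 against 2 reads (99.8, interval 27.4 to 828) and C1qtnf3 243 against 2 (81.1, interval 22.2 to 673), and Ibsp fell from 19.7 ± 21.6 to 0.376 ± 0.118 CPM. The edgeR adjusted p of Col8a2 and Ibsp (0.0108 and 0.00611) became 0.244 and 0.194 with voom and 0.0616 and 0.053 with a robust fit, and over 16 alternatives ran from 1.02e-33 to 0.244 and from 1.15e-69 to 0.194. Without vehicle replicates 1 and 2 the log2 change was -4.09 and -7.32 for Col8a2 (-6.43 with all libraries) and -3.61 and -6.57 for Ibsp (-5.70). Without LCL161 plus LTα1β2 replicate 1, which held no read of Sp7 or C1qtnf3, it was -6.43 for Sp7 (-7.37) and -5.22 for C1qtnf3 (-6.17). Beside these genes, 12 of 13 stromal markers were lower (12 adjusted over the list alone), with a median of -3.38 (camera adjusted p = 6.5e-09; adjusted p = 0.411 with an estimated correlation).

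Of the pathway genes, Nfkb2 was 2.49 (SE 0.11) higher than in vehicle on the log2 scale, Relb 2.38 (SE 0.16), Birc3 2.35 (SE 0.09), Traf2 1.27 (SE 0.11), Birc2 1.24 (SE 0.10) and Traf3 1.13 (SE 0.13), with edgeR adjusted p from 1.9e-06 to 0.000391. Xiap (0.33, adjusted p = 0.095) did not pass. Ltbr (0.0085, adjusted p = 0.954) did not pass either, but it was lower under total-count scaling (-0.31, adjusted p = 0.0281). Map3k14 was higher by 0.41 (SE 0.12, edgeR adjusted p = 0.0274), a call lost without vehicle replicate 1 (0.221), vehicle replicate 2 (0.136), LTα1β2 replicate 2 (0.0758), and LCL161 plus LTα1β2 replicates 1 (0.0831) and 2 (0.106). Its adjusted p ran from 0.0149 to 0.544 over 16 alternatives. Of the 21 machinery genes, 16 rose and Otud7b fell (17 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 1.04e-07; adjusted p = 0.324 with an estimated correlation). Of 24 NF-kB feedback genes, 23 rose and Ier3 fell (23 and 1 adjusted over the list alone), with a median of 2.38 (camera adjusted p = 6.82e-15; adjusted p = 0.324 with an estimated correlation), including Sod2 (3.60, SE 0.11) and Icam1 (4.43, SE 0.14).

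All 35 interferon-stimulated genes (median 3.50), all 22 interferon-gamma-type genes (6.20) and all 21 class I genes (3.31) were higher than in vehicle, with the same counts adjusted over the list alone. Their camera adjusted p was 7.63e-21, 7.63e-21 and 1.21e-19, and adjusted p = 0.388, 0.268 and 0.264 with an estimated correlation. Of 13 class II genes, 12 rose and Lgmn fell (12 and 1 adjusted over the list alone), with a median of 4.27 (camera adjusted p = 1.97e-08; adjusted p = 0.324 with an estimated correlation). Of 19 costimulatory and checkpoint genes, 14 rose and Vsir and Cd80 fell (15 and 2 adjusted over the list alone), with a median of 2.25 (camera adjusted p = 5e-07; adjusted p = 0.264 with an estimated correlation), and Cd274 reached 1626 ± 16.8 CPM. Cytokines (12 higher, Csf1, Osm and Vegfa lower, of 20; 12 and 3 adjusted over the list alone) had a median of 1.83 (camera adjusted p = 0.00834; adjusted p = 0.415 with an estimated correlation). Chemokines (14 higher, Ccl6, Cxcl14, Cx3cl1 and Ccl17 lower, of 21; 14 and 5 adjusted over the list alone) had a median of 1.43 (camera adjusted p = 0.00101; adjusted p = 0.379 with an estimated correlation). Ccl22 had 3 reads in vehicle and 918 with LCL161 plus LTα1β2, a ratio of 459 (95% counting interval 156 to 2230).

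Of 30 proliferation genes, 28 were lower than in vehicle (28 adjusted over the list alone), with a median of -2.09 (camera adjusted p = 1.31e-15; adjusted p = 0.324 with an estimated correlation), while Pcna (0.14) and E2f1 (0.23) did not pass. Neutrophil markers (9 lower, Ly6g and Csf3r higher, of 14; 9 and 2 adjusted over the list alone) had a median of -1.56 (camera adjusted p = 0.0224; adjusted p = 0.638 with an estimated correlation). That adjusted p was 0.113 by fry and 0.0734 under total-count scaling, and ran from 1.13e-05 to 0.638 over 12 alternatives. Of 23 cholesterol synthesis genes, 16 fell and Mvd rose (16 and 1 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 8.64e-06; adjusted p = 0.264 with an estimated correlation). Of 26 genes of glycolysis and hypoxia, 18 rose and Adm, Ndrg1 and Vegfa fell (18 and 3 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 6.1e-05; adjusted p = 0.415 with an estimated correlation). Of 18 NRF2 and oxidative stress genes, 11 rose and Nqo1 fell (12 and 2 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 0.00051; adjusted p = 0.426 with an estimated correlation). Of 27 cell death genes, 11 rose and Pmaip1, Ripk3 and Bcl2l1 fell (11 and 3 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.0116; adjusted p = 0.368 with an estimated correlation). Of 13 dendritic cell markers, 8 rose and Fscn1 fell (9 and 1 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 0.00622; adjusted p = 0.324 with an estimated correlation). Bst2 is also in the interferon-stimulated list, Itgax and Cd209a among the phagocytic receptors and Ccr7 among the costimulatory genes. The dendritic list is therefore not independent of those lists, and its call alone does not show dendritic cells.

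The remaining lists were not called against vehicle, with camera adjusted p of 0.586 for noncanonical targets, 0.683 for phagocytic receptors, 0.0537 for lysosomal genes (0.00523 without vehicle replicate 2), 0.0954 for alternative activation, 0.314 for macrophage lineage genes, 0.367 for osteoclast genes, 0.653 for LXR targets and 0.653 for the unfolded protein response. The same held for markers of T and NK cells (0.838), B cells (0.838), mast cells (0.863) and erythroid cells (0.0954, and 0.0215 without vehicle replicate 1). By fry, noncanonical targets (adjusted p = 0.0119) and osteoclast genes (0.0152) passed as higher. Alternative activation (0.00227) and erythroid cells (0.0323) passed as lower by fry. Of the phagocytic receptors 13 rose and 11 fell (14 and 12 adjusted over the list alone), and of the macrophage lineage genes 10 rose and 6 fell (11 and 6 adjusted over the list alone). Within them, Mrc1 fell from 119 ± 14.4 to 5.22 ± 0.878 CPM and Cx3cr1 from 82.2 ± 5.92 to 7.39 ± 0.276 CPM.

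Genes that changed against vehicle with LTα1β2 were compared with those that changed with LCL161 plus LTα1β2. Both comparisons called 1540 genes higher and 1660 lower, where independent lists would share 444 and 420. Simulated unchanged groups that shared simulated vehicle libraries had 0 calls in common. With no changed gene in them, almost no gene can be called, so that 0 does not measure how far shared libraries raise the overlap. Leaving out vehicle replicate 1 gave 822 and 722 genes, leaving out LTα1β2 replicate 2 gave 980 and 1086, and leaving out LTα1β2 replicate 1 gave 638 lower genes. Under total-count scaling 1048 higher and 3209 lower genes were shared. With a vehicle library of its own for each treatment, an alternative chosen after the data were seen, 996 higher and 1048 lower genes were shared with vehicle replicate 1 for LTα1β2, where independent lists would share 178 and 197. The other way round, 863 and 718 were shared, where independent lists would share 137 and 137. Across genes, the log2 changes correlated at 0.671, where simulated unchanged groups gave 0.455, and their covariance exceeded the simulated one (0.84 against 0.0905) by 0.749. Of the genes higher with LTα1β2, 493 rose further with LCL161 and 593 fell, and of the genes lower with LTα1β2, 862 fell further and 161 rose, where independent lists would share 255, 364, 301 and 211. These counts share the LTα1β2 libraries, against which simulated unchanged steps correlated at -0.487 and the observed steps at -0.028.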

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

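The scaling by total counts and the division of the vehicle libraries were chosen after the results were seen, and the other alternatives were planned. The counts of changed genes stayed within 1.5 times under relative log expression factors, DESeq2, voom, both filters, the newer and the robust quasi-likelihood fits, the groups compared alone and total-count scaling. With a 2-fold minimum, which removes smaller changes by construction, they were 2106, 2585 and 4374. Leaving out each library in turn gave 1930 to 4933 genes for LTα1β2 against vehicle, 2332 to 4604 for LCL161 plus LTα1β2 against LTα1β2 and 4885 to 7285 for LCL161 plus LTα1β2 against vehicle, 822 to 1862 shared higher and 638 to 1743 shared lower genes, and 44 to 48 list calls. A group left with 1 library was assumed to vary like the others, and fewer libraries enter each such fit. A vehicle library of its own for each treatment gave 996 shared higher and 1048 shared lower genes, or 863 and 718 the other way round, with fewer libraries per comparison. Total-count scaling gave 3209 shared lower genes against 1660, and it shifts all genes by construction. With an estimated correlation 0 of 87 list tests passed in camera (11 at an unadjusted p under 0.05, the lowest 0.0125), against 46 with the preset correlation and 55 by fry. The estimated correlation rests on 3 residual degrees of freedom, too few for that setting to decide these lists. Of the 46 list calls, 39 were kept in every setting but the estimated correlation, and 42 in every setting but that and fry. By fry, 14 further list tests passed (adjusted p in brackets). For LTα1β2 against vehicle, cytokines (0.0279) and dendritic cells (0.00357) were higher, and alternative activation (0.00295) and erythroid cells (0.0279) lower. In the LCL161 step, noncanonical targets (0.0147), osteoclast genes (0.009), cell death genes (0.0241) and dendritic cells (0.00234) were higher. Phagocytic receptors (0.0178) and alternative activation (0.0205) were lower by fry in that step. For LCL161 plus LTα1β2 against vehicle, fry called noncanonical targets (0.0119) and osteoclast genes (0.0152) higher. It called alternative activation (0.00227) and erythroid cells (0.0323) lower there. Of 249 calls of genes selected by the rule, 229 were kept in every setting and 20 lost in at least 1. With no filter beyond 1 read, camera turned from higher to lower for 2 lists not called for LCL161 plus LTα1β2 against LTα1β2. These were interferon-gamma-type genes (-0.20, camera adjusted p = 0.0238, against 0.51 in the main fit) and unfolded protein response (-0.18, 0.0129 against 0.999). Their medians were already below 0 in the main fit (-0.062 and -0.042). Without that filter the median of all 47056 genes was 0.208, against 0.0045 with it (0.431 and 0.047 for LCL161 plus LTα1β2 against vehicle). Camera compares a list with the other genes, so lists called lower in that setting can reflect this raised background. Whether it accounts for the calls was not tested. That setting also called phagocytic receptors (0.000262), lysosomal genes (1.13e-05), alternative activation (0.00379) and LXR targets (0.0029) lower there. It called alternative activation (0.00394) and erythroid cells (0.0014) lower for LCL161 plus LTα1β2 against vehicle, and for LTα1β2 against vehicle cytokines (0.0144) and dendritic cells (0.046) higher and erythroid cells (0.043) lower. Ltbr against vehicle turned to -0.31 under total-count scaling (adjusted p = 0.0281).

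The replicate numbers are shared by label alone. With the number as a block, 4144, 4629 and 7308 genes changed, 47 list tests passed, and 1504 higher and 1514 lower genes were shared. The list call gained was that of lysosomal genes, higher for LCL161 plus LTα1β2 against vehicle (camera adjusted p = 0.0486). In the check of pairing, deviations of same-numbered libraries correlated across genes at 0.138, 0.157 and 0.0941, and over the 9865 genes above 8 CPM at -0.265, -0.0139 and 0.179. Depth limits the low genes: in simulated data, recovery of 2-fold changes over all genes was 54.5% to 58.8%.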

Other observations

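The tests of list differences by shared reads and by starting level were written before their results were seen. All other tests below, and the added lists, were chosen after. The p-values of the added lists therefore describe these data and are not independent evidence.

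Complement genes rose with LTα1β2: of 17 tested in a list written after the leading genes were seen, 11 rose and C5ar1 fell, with a median of 1.21 (camera adjusted p = 3.76e-07; adjusted p = 0.144 with an estimated correlation). C3 went from 69 and 72.9 CPM in vehicle to 553 and 645 CPM with LTα1β2 and 3593 and 3584 CPM with LCL161 plus LTα1β2, and Cfb from 3.7 and 3.46 to 377 and 415 and then 2573 and 3040 CPM, although exons of Cfb overlap another gene on the same strand and counts of C3 were not whole. In the LCL161 step C3 and Cfb rose while 8 members fell (camera adjusted p = 0.104), and against vehicle 11 rose and 4 fell (camera adjusted p = 0.00789; adjusted p = 0.312 with an estimated correlation). Of 17 pattern sensor genes, 13 rose and Tlr7 fell with LTα1β2 (median 1.05, camera adjusted p = 1.24e-06; adjusted p = 0.144 with an estimated correlation), 6 rose and 6 fell with LCL161 (median 0.070, and -0.053 under total-count scaling, camera adjusted p = 0.397), and 13 rose and Tlr13, Tlr8 and Tlr5 fell against vehicle (camera adjusted p = 5.25e-05; adjusted p = 0.199 with an estimated correlation). Of 14 C-type lectin genes, 6 rose and Clec4a2 and Clec4d fell with LTα1β2 (camera adjusted p = 0.0358; adjusted p = 0.343 with an estimated correlation), the LCL161 step was not called (camera adjusted p = 0.0603), and 8 rose and 3 fell against vehicle, Clec4a2, Clec4b1 and Clec10a (camera adjusted p = 0.00601; adjusted p = 0.312 with an estimated correlation).

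Prostanoid genes moved both ways, and their list was not called in any comparison (camera adjusted p = 0.699, 0.899 and 0.723 in the order of the report). Ptges, the inducible prostaglandin E synthase, went from 14.6 and 16.6 CPM in vehicle to 24.1 and 28.5 CPM with LTα1β2 and 767 and 892 CPM with LCL161 plus LTα1β2. Hpgd, which degrades prostaglandins, was at 7.96 and 12.8 CPM, then 5.42 and 3.42, then 0.438 and 0.23 CPM. Iron handling genes were not called either (camera adjusted p = 0.802, 0.323 and 0.775). Of 19 genes known to be raised by endotoxin, 15 rose and Lcn2 fell in the LCL161 step, with a median of 2.45 (camera adjusted p = 2.63e-13; adjusted p = 0.144 with an estimated correlation), and 16 rose against vehicle (camera adjusted p = 2.88e-09; adjusted p = 0.144 with an estimated correlation). Tnf, Il12b, Cxcl2, Ccl3 and Ptgs2 are also in the cytokine, chemokine or NF-kB feedback lists, so these tests partly repeat results given above. Ifnb1 had 1 and 2 reads in vehicle, 3 and 5 with LTα1β2 and 10 and 13 with LCL161 plus LTα1β2 (edgeR adjusted p = 0.231 for LTα1β2, 0.0632 for the LCL161 step and 0.00744 against vehicle). Lta, a subunit of the ligand itself, had 0 and 2, then 1 and 0, then 25.5 and 19.5 reads (edgeR adjusted p = 0.00706 in the LCL161 step).

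The rise of interferon-gamma-type genes with LTα1β2 was not removed by scaling: under total-count scaling the median log2 change of the 22 genes was 5.78 instead of 5.98. The TMM factors lay between 0.874 and 1.15, so a change of scaling could not have removed a rise of that size. Endotoxin in the ligand preparation cannot be told apart from the ligand, because no group here separates them. The endotoxin list did not rise as a set with LTα1β2 (median 0.080, and -0.11 under total-count scaling; camera adjusted p = 0.849). Of its genes 4 rose (Tnf, Saa3, Ptges and Il12b) and 4 fell (Cxcl2, Ptgs2, Ccl3 and Cxcl1), which at 24 h alone does not decide the question. Interferon gamma made by T or NK cells in the culture may also contribute: Ifng had 0 reads in the LTα1β2 libraries and 1 and 1 in vehicle, below the floor of 3, and none of 8 T and NK cell markers changed, but a small number of cells, or transcription before 24 h, cannot be told apart at this depth. Interferon gamma protein in a reagent, and a direct response of macrophages to the ligand, stay open and were not tested.

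The fall of stromal markers in both steps was not removed by scaling either, with medians of -1.56 or lower under total-count scaling. That scaling moves log2 changes downwards in both steps, so it could not have removed the fall. The vehicle libraries held 2741 and 1699 CPM of Col1a1 and 1785 and 1454 CPM of Sparc, and 161 and 178 CPM and 176 and 184 CPM remained with LCL161 plus LTα1β2, so a smaller share of stromal cells in the cultures is a candidate explanation. Further stromal genes outside the matrix had medians of -0.86 with LTα1β2 and -1.16 with LCL161, against -1.24 and -1.85 for further matrix genes, which leaves a smaller share of these cells and lower expression within them unable to be told apart. The marker Cxcl12 and the further gene Axl are also in other lists, and no library of sorted cells was used here.

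LCL161 moved the interferon-stimulated list more than the interferon-gamma-type list: the difference of median log2 changes was 1.25, which was seen before any test, so that permuting the genes afterwards adds no evidence, and the interferon-stimulated list had adjusted p = 0.415 with an estimated correlation. Shared reads cannot be told apart as a source, because only 5 and 3 members had whole counts in all libraries (difference 1.22, permutation p = 0.214 over genes, which are not independent replicates). A higher starting level of the interferon-gamma-type genes may limit their further rise: over the 12 and 2 members between 77.1 and 243 CPM with LTα1β2 the difference was 1.52 (permutation p = 0.0106), but 2 genes are too few to exclude it. That range was first set between quartiles, which did not overlap (upper quartile 171 CPM, lower quartile 264 CPM), and was widened once, before a difference over either range was computed. The cause of the difference was not tested further.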
